A study of Sus scrofa with 36 samples.

How the data were processed

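Poly(A) RNA was sequenced in 36 libraries of cultured pig cells, in 12 groups of 3 defined by cell type, medium and day. Per the labels, AVIC were primary cells of passage 2 to 6 grown in DMEM with 10% fetal bovine serum and antibiotics, and AVSMC were bought and grown in the vendor's medium. The labels call the control medium conditioned medium but describe it as this growth medium, and here it is CM. The composition of OM was not given, and 2.5 mM phosphate was given for Pi. The treatment entries of the OM libraries, and the titles of the 3 AVIC OM day 5 libraries, carry the abbreviation CM after the words for osteogenic medium. The OM reading was used because the descriptions give OM and the words name osteogenic medium in every case. The titles of the same 3 libraries also say 3 days while their descriptions and treatment entries say day 5, and they were grouped as day 5. Whether replicates were separate cultures, and whether they share an origin across media, was not stated.

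Per the labels, the authors trimmed the reads, mapped them to Sscrofa11.1 with HISAT2 and assembled transcripts with StringTie, with versions and strand setting not stated. Library preparation is described with both a Universal Plus mRNA-Seq kit and a TruSeq Stranded mRNA kit, so the strand setting could not be settled. The authors deposited a table of counts per gene and library, which was used for the main results. The authors also deposited FPKM per gene in the same table, fragment counts scaled by transcript length and mapped total, which served as an alternative. The deposited counts are whole numbers, and of 1990 low counts, up to 20, 96.4% equalled the FPKM-based estimate rounded up to the next whole number within 0.05 reads, against 50.3% for the nearest whole number. The ratio of count to FPKM deviated by 0.27% at the 99th percentile. The table held 28232 genes, of which 19562 were protein coding, and 7952 of all genes had no count in any library. A total of 24 entries had no symbol and held 0.022% of counts. Gene IDs matched the RefSeq gene table in 28208 cases, from which positions were taken. The deposited table of transcripts holds the same reads split by isoform and was not used. Total counts per library ran from 37409132 to 56053906, and intervals and floors given for counts cover counting error only.

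Genes were filtered with filterByExpr, normalised with TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust estimation, then glmQLFTest) in R 4.3.3. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. One model with a mean per group was fitted to the 18 libraries of AVIC (14760 genes, 12 residual degrees of freedom) and another to those of AVSMC (14714 genes, 12). Comparisons between cell types used a model of all 36 libraries (15507 genes, 24). TMM factors ran from 0.928 to 1.061 in AVIC, 0.909 to 1.066 in AVSMC and 0.893 to 1.073 in all libraries. The SE of a log2 change was its size divided by the square root of the F statistic. For each cell type, OM and Pi were compared with CM and with each other on each day, CM was compared between days, and the change of each response between days was tested as an interaction, 9 comparisons a cell type. AVSMC and AVIC were compared in CM on each day, and the OM and Pi responses were compared between cell types, so that 24 comparisons were made in all. The p-values measure only the spread between these libraries. Levels are CPM with TMM factors. Where a group had no count, the fold was computed against a floor of 3 counts over the group.

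The 26 gene lists were written from general knowledge and held 561 entries, of which 18 could not be matched to the table, 3 others being matched by a synonym. They covered glucocorticoid-responsive, bone and mineralisation, cartilage, phosphate transport and calcification inhibitor, smooth muscle contractile, collagen and fibrous matrix, and matrix protease and inhibitor genes. TGF-beta, BMP, Wnt, Notch, ERK, inflammatory, interferon, cell cycle, p53, unfolded protein response and ATF4, oxidative stress, adipocyte, hypoxia and glycolysis, and cholesterol synthesis genes were included. Marker lists were cardiac and valve positional genes, HOX genes, and fibroblast, endothelial, and leukocyte and macrophage markers. Each list with at least 5 tested members was tested against all other genes with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Adjustment was over the lists of a comparison, and the same test was run with the correlation estimated from the data. Counts given as adjusted over the list alone apply Benjamini-Hochberg to the members of the list only. The rule for named genes took a panel of 22 genes, and the 5 largest changes in each direction among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between the groups' libraries, except in interactions. It also took up to 4 genes per list by smallest adjusted p, for lists that were called or had at least 3 called members. Results for some genes that met this rule are not reported here, though counts over named genes hold them.

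The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, the compared groups fitted alone, 1 fit of 36 libraries for comparisons within a cell type, limma on log2 FPKM with a pseudocount of 0.1 or 1, a block for replicate number, leaving out each library in turn, and for lists a prior count of 0.5. Library totals without TMM factors were added after the data had been seen, while the comparisons, the gene lists, the rule for named genes and the other alternatives were fixed before the data were examined. Other splits of the libraries were refitted, all 10 for a comparison of 3 against 3 and 100 drawn for each interaction. The procedure was tested on simulated data built from these libraries, in which changes of 0.5, 1 and 2 on the log2 scale were recovered in 82.1%, 98.5% and 100% of changed genes for OM in AVIC at day 3 and in 44.8%, 95.5% and 100% for Pi in AVSMC at day 3. Only a small set of well counted genes was changed, in 1 group, and all other genes had equal means in all groups. These shares therefore do not cover genes with low counts or data in which many genes change. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.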

Results

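RNA was sequenced from 2 kinds of cultured pig cells. Aortic valve interstitial cells (AVIC) are the fibroblast-like cells of the valve leaflet, and aortic vascular smooth muscle cells (AVSMC) are the contractile cells of the arterial wall. Both were kept in control medium (CM), in osteogenic medium (OM), whose composition the labels do not give, or with 2.5 mM phosphate (Pi), and were harvested after 3 or 5 days. The 12 groups of cell type, medium and day held 3 libraries each, 36 in all. The series title names calcification in both cell types as the subject. Total counts ran from 37409132 to 56053906 per library. Levels are CPM, counts scaled by a library's normalised total, given as mean ± SD with n = 3. Values after a gene's name are log2 fold changes ± SE from the fitted model, with n = 3 per group. Gene positions refer to the Sscrofa11.1 assembly. RUNX2, MYH11, FKBP5, ZBTB16, NT5E, VEGFA, INMT, PCSK1, COL11A1, ADAMTS1, TIMP3, CA12, DKK2, SPRY1, PTGS2, MYOCD, POSTN and HOXC8 each overlap another annotated gene, and the strand setting of the counts was not stated.

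In AVIC, OM against CM at day 3 asks how valve cells responded early to osteogenic medium. Genes that glucocorticoids induce were among the clearest increases. ZBTB16 (gene ID 100625290, chromosome 9 from 41639536 to 41839254) encodes a transcription factor that glucocorticoids induce. It stood at 36.8 ± 2.56 CPM in OM against 0.0873 ± 0.0998 in CM, a log2 change of 8.63 ± 0.36, adjusted p = 8.4e-16. FKBP5 (gene ID 100155423, chromosome 7 from 31441764 to 31550704) encodes a co-chaperone of the glucocorticoid receptor and rose from 59.1 ± 0.816 to 155 ± 5.19 CPM. PSAT1 (gene ID 100154160, chromosome 1 from 231142673 to 231172364), an enzyme of serine synthesis controlled by the stress factor ATF4, changed by -4.10 ± 0.08, adjusted p = 3.3e-19. The smooth muscle myosin gene MYH11 (gene ID 100627924, chromosome 3 from 7002667 to 7143093) rose from 8.28 ± 0.0567 to 106 ± 12.8 CPM. ACTA2 (gene ID 733615, chromosome 14 from 100868145 to 100886732), encoding smooth muscle alpha-actin, stood at 2157 ± 82.8 CPM in CM and 2505 ± 28.6 in OM and was not called (0.21 ± 0.11). In all, 7304 of 14760 genes were called, 3664 higher and 3640 lower in OM, 1270 of them by at least 2-fold.

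Of 20 glucocorticoid-responsive genes, 18 rose and none fell (19 and 0 adjusted over the list alone, adjusted p = 2.09e-11). PER1 (2.40 ± 0.07), SGK1 (2.57 ± 0.08) and FKBP5 (1.39 ± 0.06) were among those that rose. Contractile genes rose in 14 and fell in 1 of 18 cases (14 and 1 adjusted over the list alone, adjusted p = 1.75e-05), with ACTG2 at 3.03 ± 0.13 and the smooth muscle coactivator MYOCD at 2.42 ± 0.14. Among 21 inflammatory genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 3.75e-07). The neutrophil chemokine gene CXCL8 (gene ID 396880, chromosome 8 from 69932646 to 69935861) rose from 3.42 ± 0.352 to 49.3 ± 7.09 CPM. There were 12 rises and 5 falls among the 20 matrix proteases and inhibitors tested (12 and 5 adjusted over the list alone, adjusted p = 0.00415), with ADAMTS1 (3.46 ± 0.08) and ADAMTS5 (1.91 ± 0.07) higher. Of 30 unfolded protein response and ATF4 genes, 5 rose and 22 fell (5 and 22 adjusted over the list alone, adjusted p = 8.63e-11). ASNS (-2.48 ± 0.06), PHGDH (-2.47 ± 0.07) and TRIB3 (-2.46 ± 0.07), all ATF4 targets, fell. Hypoxia and glycolysis genes rose in 3 and fell in 21 of 26 cases (3 and 22 adjusted over the list alone, adjusted p = 5.83e-08), with the oxygen sensor EGLN3 at -3.44 ± 0.08. These 6 list calls held with an estimated correlation between genes, and the next 9 did not. Among 22 cholesterol synthesis genes, 18 rose and none fell (19 and 1 adjusted over the list alone, adjusted p = 6.06e-08, or adjusted p = 0.07 with an estimated correlation). There were 2 rises and 12 falls among the 15 oxidative stress genes tested (2 and 12 adjusted over the list alone, adjusted p = 4.09e-06, or adjusted p = 0.0684 with an estimated correlation), with the ferritin gene FTL at -1.86 ± 0.04. Of 37 cell cycle genes, 20 rose and none fell (21 and 0 adjusted over the list alone, adjusted p = 0.000305, or adjusted p = 0.567 with an estimated correlation). ERK-responsive genes rose in 12 and fell in 4 of 20 cases (12 and 5 adjusted over the list alone, adjusted p = 0.0069, or adjusted p = 0.139 with an estimated correlation). Among 26 collagen and fibrous matrix genes, 14 rose and 6 fell (14 and 7 adjusted over the list alone, adjusted p = 0.0234, or adjusted p = 0.453 with an estimated correlation), with ELN higher (2.07 ± 0.08) and COL6A3 lower (-1.57 ± 0.07). There were 10 rises and 3 falls among the 15 BMP responsive genes tested (11 and 3 adjusted over the list alone, adjusted p = 0.0234, or adjusted p = 0.139 with an estimated correlation), and the BMP antagonist GREM1 fell (-2.47 ± 0.08). Of 27 interferon-stimulated genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone, adjusted p = 0.0356, or adjusted p = 0.567 with an estimated correlation), a call that also ended without replicate 1 of every group (0.077). p53 targets rose in 2 and fell in 10 of 20 cases (2 and 10 adjusted over the list alone, adjusted p = 0.0234, or adjusted p = 0.139 with an estimated correlation). Among 14 endothelial markers, 2 rose and 10 fell (2 and 10 adjusted over the list alone, adjusted p = 0.0184, or adjusted p = 0.183 with an estimated correlation). CDH5 (-0.62 ± 0.06) and NOS3 (-2.16 ± 0.17) fell while PLVAP (5.34 ± 0.46) rose.

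The remaining lists were not called. There were 6 rises and 4 falls among the 17 bone and mineralisation genes tested (6 and 4 adjusted over the list alone, adjusted p = 0.791). RUNX2 (gene ID 100737965, chromosome 7 from 40106581 to 40353304), the osteoblast transcription factor gene, nevertheless rose from 71.7 ± 2.23 to 132 ± 4.12 CPM (0.88 ± 0.08, adjusted p = 3.3e-08). SPP1 (gene ID 397087, chromosome 8 from 131077786 to 131085334), encoding osteopontin, rose from 17.1 ± 2.38 to 37.5 ± 0.620 CPM (1.13 ± 0.15, adjusted p = 1.8e-05). ALPL, the alkaline phosphatase gene of mineralising cells, averaged at most 0.104 ± 0.0941 CPM in any group and was too low to test. Of 14 phosphate transport and calcification inhibitor genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone, adjusted p = 0.643), with ENPP1 higher (1.27 ± 0.09) and the phosphate transporter SLC20A1 lower (-0.52 ± 0.05). Cartilage genes rose in 5 and fell in 1 of 12 cases (5 and 1 adjusted over the list alone, adjusted p = 0.208). Among 18 TGF-beta responsive genes, 10 rose and 6 fell (10 and 6 adjusted over the list alone, adjusted p = 0.265). There were 8 rises and 4 falls among the 16 Wnt responsive genes tested (8 and 4 adjusted over the list alone, adjusted p = 0.175). Of 10 Notch genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.943). Adipocyte genes rose in 2 and fell in 4 of 12 cases (2 and 4 adjusted over the list alone, adjusted p = 0.925). Among 13 cardiac and valve positional genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.882), where the median was 0.03 while the test pointed down. There were 9 rises and 5 falls among the 17 fibroblast markers tested (9 and 5 adjusted over the list alone, adjusted p = 0.162). Of 7 leukocyte and macrophage markers, 1 rose and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.943). HOX genes had too few tested members in AVIC. With library totals alone in place of TMM factors, 45.3% of called genes were higher, against 50.2%.

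At day 5 the comparison asks what the response had become. HSPA5 (gene ID 407060, chromosome 1 from 265930044 to 265934959), encoding the main chaperone of the endoplasmic reticulum, stood at 6938 ± 734 CPM in OM against 497 ± 13.4 in CM, 14.0-fold higher (3.81 ± 0.06, adjusted p = 1.9e-24). ACTA2 fell from 6922 ± 97.8 to 1085 ± 17.8 CPM (-2.67 ± 0.12, adjusted p = 1.4e-10), and MYH11 (-2.48 ± 0.14) and CNN1 (-1.91 ± 0.11) fell with it. SPP1 rose from 7.35 ± 1.17 to 101 ± 22.4 CPM (3.79 ± 0.16, adjusted p = 2.0e-11), and RUNX2 by 0.40 ± 0.08. The bone sialoprotein gene IBSP (gene ID 397137, chromosome 8 from 131208281 to 131222048) reached 1.12 ± 0.257 CPM in OM. It had no count in CM, so that it was at least 49.2-fold higher with 3 counts over the group as the floor. Of 14760 genes, 8285 were called, 4261 higher and 4024 lower, 1841 of them by at least 2-fold. Unfolded protein response and ATF4 genes rose in 25 and fell in 2 of 30 cases (25 and 2 adjusted over the list alone, adjusted p = 3.57e-14), with SDF2L1 (5.64 ± 0.10) and PDIA4 (1.99 ± 0.04) higher. Among 18 contractile genes, 2 rose and 14 fell (2 and 14 adjusted over the list alone, adjusted p = 2.15e-07). There were 16 rises and 2 falls among the 20 glucocorticoid-responsive genes tested (16 and 2 adjusted over the list alone, adjusted p = 3.94e-07), with FKBP5 at 2.36 ± 0.06. These 3 calls held with an estimated correlation, and those that follow did not. Of 26 hypoxia and glycolysis genes, 18 rose and 3 fell (18 and 5 adjusted over the list alone, adjusted p = 1.7e-05, or adjusted p = 0.113 with an estimated correlation), with CA12 (2.69 ± 0.07) and VEGFA (1.32 ± 0.06) higher. Collagen and fibrous matrix genes rose in 16 and fell in 5 of 26 cases (17 and 5 adjusted over the list alone, adjusted p = 0.00197, or adjusted p = 0.373 with an estimated correlation). DCN (1.74 ± 0.05), ELN (1.41 ± 0.05) and COL3A1 (0.93 ± 0.05) rose, while COL1A1 was not called (-0.07 ± 0.05). Among 17 fibroblast markers, 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.00134, or adjusted p = 0.076 with an estimated correlation), with PDGFRA at 1.79 ± 0.05. There were 13 rises and 3 falls among the 20 ERK-responsive genes tested (14 and 3 adjusted over the list alone, adjusted p = 0.00122, or adjusted p = 0.104 with an estimated correlation), with DUSP4 at 1.61 ± 0.08. Of 20 p53 targets, 4 rose and 13 fell (4 and 13 adjusted over the list alone, adjusted p = 0.00309, or adjusted p = 0.076 with an estimated correlation), with CDKN1A at -1.16 ± 0.05. Endothelial markers rose in 3 and fell in 8 of 14 cases (3 and 8 adjusted over the list alone, adjusted p = 0.0206, or adjusted p = 0.277 with an estimated correlation), with CDH5 (-1.08 ± 0.07) and TIE1 (-1.61 ± 0.11) lower. The bone list was not called at day 5, as 5 of 17 bone and mineralisation genes rose and 5 fell (6 and 5 adjusted over the list alone, adjusted p = 0.936). AVIC OM day 5 replicate 3 stood apart from its fellows, with a chi-square per degree of freedom of 30.19 and 23.41 against counting noise. Without replicate 3 of every group, the cell cycle list went from adjusted p = 0.118 to 8.3e-09 and endothelial markers from 0.0206 to 0.0643. With library totals alone 44.7% of called genes were higher, against 51.4%.

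**Figure D1:**
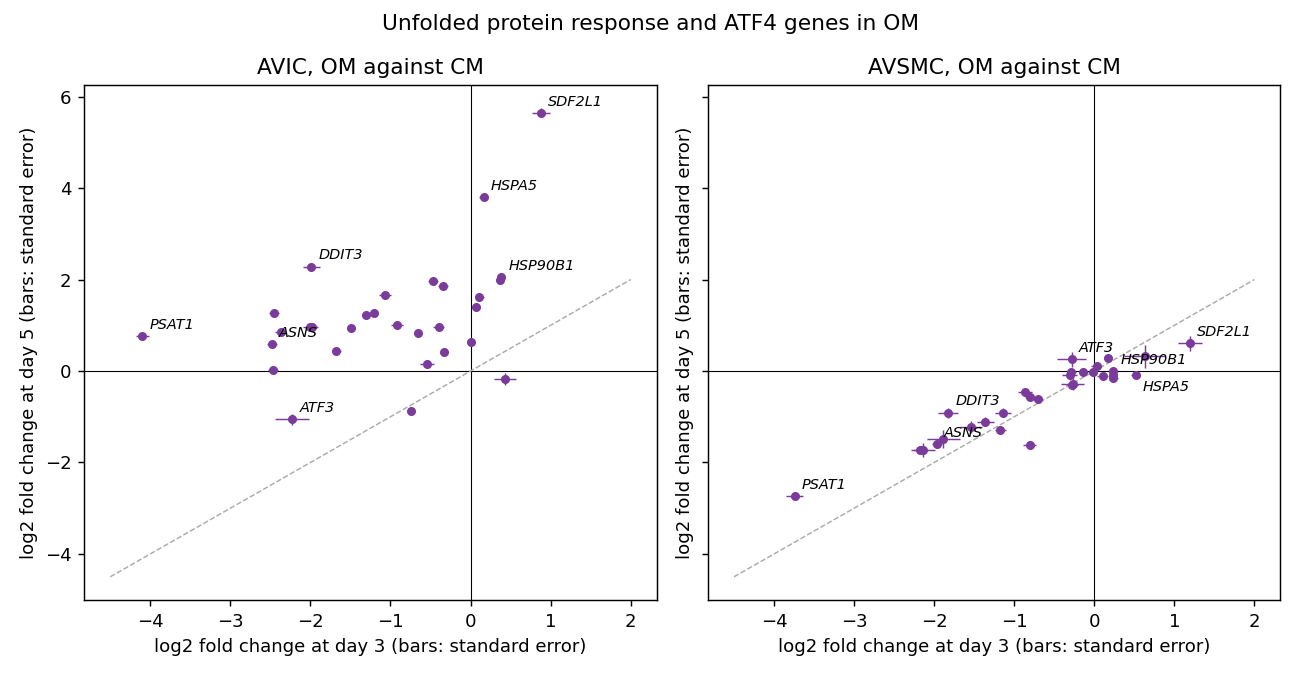
Log2 fold change of unfolded protein response and ATF4 genes in OM against CM at day 3 (horizontal) and day 5 (vertical), in AVIC (left) and AVSMC (right), with points for genes, bars for the standard error (n = 3 per group) and a dashed line for equal change. The list medians were -0.83 at day 3 and 0.97 at day 5 in AVIC, and -0.3 and -0.3 in AVSMC.

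The difference between days was itself tested as the OM change at day 5 minus that at day 3. In AVIC it was called in 6249 genes, 3375 more positive and 2874 more negative at day 5. HSPA5 differed by 3.65 ± 0.07, adjusted p = 2.7e-21, TRIB3 by 3.73 ± 0.08 and PSAT1 by 4.86 ± 0.10. PSAT1, lower in OM at day 3, stood at 523 ± 68.5 CPM in OM and 310.4 ± 8.15 in CM at day 5. MYH11 (-6.15 ± 0.20) and ACTA2 (-2.88 ± 0.16) differed in the other direction. 28 of 30 unfolded protein response and ATF4 genes were more positive and 1 more negative (28 and 2 adjusted over the list alone, median 2.32, adjusted p = 3.75e-31). Of 26 hypoxia and glycolysis genes, 23 were more positive and 0 more negative (23 and 0 adjusted over the list alone, median 0.86, adjusted p = 1.36e-15). Contractile genes numbered 1 more positive and 17 more negative of 18 tested (1 and 17 adjusted over the list alone, median -1.8, adjusted p = 6.06e-14). Each of these list calls held with an estimated correlation. In CM the contractile median itself rose by 0.99 from day 3 to day 5, which enters the contractile difference. The unfolded protein response and ATF4 list pointed down in CM between days, which enters its difference. That list was not called in the main setting (adjusted p = 0.0542) but was without the filter (0.0344). On both days 1939 genes were called higher and 1826 lower in OM, against 1057.7 and 992.4 if the calls were independent. A further 521 went from higher to lower and 703 from lower to higher. For these no number expected if independent was computed, so their counts alone do not show reversed responses.

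Pi against CM in AVIC asks how valve cells responded to raised phosphate alone. At day 3 ACTA2 fell from 2157 ± 82.8 to 477 ± 33.2 CPM (-2.18 ± 0.12, adjusted p = 6.3e-09), with MYH11 (-1.83 ± 0.27) and the calponin gene CNN1 (-1.33 ± 0.12). INMT (gene ID 100512997, chromosome 18 from 42213335 to 42218175), an indolethylamine methyltransferase gene, rose from 1.02 ± 0.144 to 31.4 ± 3.42 CPM (4.93 ± 0.25, adjusted p = 2.7e-10). BMP2 (gene ID 100157103, chromosome 17 from 15750487 to 15762982), a bone morphogenetic protein gene, rose from 12.2 ± 0.474 to 39.2 ± 0.501 CPM (1.68 ± 0.07, adjusted p = 6.0e-15). The phosphate transporter gene SLC20A1 (gene ID 100518065, chromosome 3 from 43844716 to 43860547) rose from 448 ± 6.10 to 628 ± 19.5 CPM (0.48 ± 0.04, adjusted p = 8.6e-09). RUNX2 (0.06 ± 0.08) and SPP1 (0.24 ± 0.17) were not called. Called genes numbered 4132 of 14760, 1972 higher and 2160 lower, 462 of them by at least 2-fold. Among 18 contractile genes, 0 rose and 15 fell (0 and 15 adjusted over the list alone, adjusted p = 6.38e-15). There were 20 rises and 0 falls among the 22 cholesterol synthesis genes tested (21 and 0 adjusted over the list alone, adjusted p = 3e-15), with HMGCS1 at 0.65 ± 0.05. Of 20 matrix proteases and inhibitors, 11 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 2.27e-05), with TIMP3 higher (1.46 ± 0.07). These 3 calls held with an estimated correlation, and those of the next 4 lists did not. Inflammatory genes rose in 13 and fell in 4 of 21 cases (14 and 4 adjusted over the list alone, adjusted p = 9.72e-07, or adjusted p = 0.0559 with an estimated correlation), with CXCL8 (3.45 ± 0.15) and the adhesion molecule VCAM1 (1.26 ± 0.05) higher. Among 26 collagen and fibrous matrix genes, 2 rose and 15 fell (2 and 17 adjusted over the list alone, adjusted p = 9.67e-07, or adjusted p = 0.179 with an estimated correlation), with COL11A1 at -2.06 ± 0.15. There were 11 rises and 4 falls among the 20 ERK-responsive genes tested (11 and 4 adjusted over the list alone, adjusted p = 0.00865, or adjusted p = 0.232 with an estimated correlation), with the ERK phosphatase gene DUSP4 at 2.08 ± 0.07. Of 26 hypoxia and glycolysis genes, 13 rose and 3 fell (13 and 4 adjusted over the list alone, adjusted p = 0.00436, or adjusted p = 0.36 with an estimated correlation), with VEGFA at 1.10 ± 0.06. The bone list was not called, as 2 of 17 bone and mineralisation genes rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.838). Library totals alone put 57.4% of called genes higher, against 47.7%.

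At day 5, MYH11 in AVIC stood at 0.947 ± 0.113 CPM in Pi against 61.8 ± 3.57 in CM of the same day (-6.03 ± 0.22, adjusted p = 9.7e-13). ACTA2 differed from CM by -3.78 ± 0.13, adjusted p = 6.8e-12. INMT (7.83 ± 0.29), the prohormone convertase gene PCSK1 (8.87 ± 0.56) and BMP2 (2.41 ± 0.07, adjusted p = 3.9e-19) rose. The cytokine gene IL6 (gene ID 399500, chromosome 9 from 91506421 to 91510830) rose from 9.63 ± 0.628 to 269 ± 19.6 CPM (4.80 ± 0.16). SLC20A1 (0.81 ± 0.05, adjusted p = 2.2e-13), the ectonucleotidase gene NT5E (0.84 ± 0.05) and RUNX2 (0.45 ± 0.08, adjusted p = 1.4e-04) rose. MGP, encoding an inhibitor of calcification (-0.96 ± 0.10), and COL1A1 (-0.99 ± 0.05) fell, and SPP1 was not called (-0.03 ± 0.24). Called genes numbered 7174 of 14760, 3460 higher and 3714 lower, 1266 of them by at least 2-fold. Among 18 contractile genes, 0 rose and 17 fell (0 and 17 adjusted over the list alone, adjusted p = 2.05e-15), a call that held with an estimated correlation, unlike those that follow. There were 4 rises and 17 falls among the 26 collagen and fibrous matrix genes tested (4 and 17 adjusted over the list alone, adjusted p = 0.000138, or adjusted p = 0.306 with an estimated correlation), with ELN at -1.48 ± 0.07. Of 30 unfolded protein response and ATF4 genes, 19 rose and 7 fell (20 and 7 adjusted over the list alone, adjusted p = 0.000917, or adjusted p = 0.142 with an estimated correlation), with CHAC1 (1.24 ± 0.05) and DDIT4 (1.10 ± 0.05) higher. ERK-responsive genes rose in 14 and fell in 4 of 20 cases (15 and 4 adjusted over the list alone, adjusted p = 0.000242, or adjusted p = 0.107 with an estimated correlation), with DUSP4 (3.33 ± 0.08) and SPRY1 (1.89 ± 0.06) higher. Among 21 inflammatory genes, 12 rose and 5 fell (12 and 5 adjusted over the list alone, adjusted p = 0.000836, or adjusted p = 0.213 with an estimated correlation), with VCAM1 at 1.97 ± 0.05. There were 0 rises and 9 falls among the 37 cell cycle genes tested (0 and 4 adjusted over the list alone, adjusted p = 0.00521, or adjusted p = 0.81 with an estimated correlation). The bone list was again not called, as 4 of 17 bone and mineralisation genes rose and 5 fell (4 and 5 adjusted over the list alone, adjusted p = 0.969). With library totals alone 68.4% of called genes were higher, against 48.2%, and the median of all genes moved by 0.129 on the log2 scale.

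The Pi response of AVIC differed between days in 2834 genes, 1339 more positive and 1495 more negative at day 5. MYH11 (-4.20 ± 0.46) and the hyaluronan-degrading gene CEMIP (-3.78 ± 0.24) were more negative, and IL6 (2.41 ± 0.21) and SPRY1 (1.23 ± 0.09) more positive. Contractile genes numbered 0 more positive and 15 more negative of 18 tested (0 and 15 adjusted over the list alone, median -0.92, adjusted p = 4.19e-16). Among 22 cholesterol synthesis genes, 0 were more positive and 19 more negative (0 and 20 adjusted over the list alone, median -0.47, adjusted p = 2.6e-18). 10 of 20 ERK-responsive genes were more positive and 0 more negative (10 and 1 adjusted over the list alone, median 0.34, adjusted p = 9.72e-06). Of 30 unfolded protein response and ATF4 genes, 17 were more positive and 4 more negative (19 and 6 adjusted over the list alone, median 0.36, adjusted p = 2.23e-06). These 4 calls held with an estimated correlation. In CM the contractile median itself rose by 0.99 from day 3 to day 5, and all 22 cholesterol synthesis genes rose. The ERK-responsive list was called lower at day 5 in CM (adjusted p = 0.00289, or adjusted p = 0.208 with an estimated correlation). For unfolded protein response and ATF4 genes the list test pointed down in CM. It was not called in the main setting (adjusted p = 0.0542) but was without the filter (0.0344). All 4 differences therefore include the change in CM and do not alone show a change within Pi. Library totals alone made 71.6% of called genes more positive, against 47.2%.

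**Figure D2:**
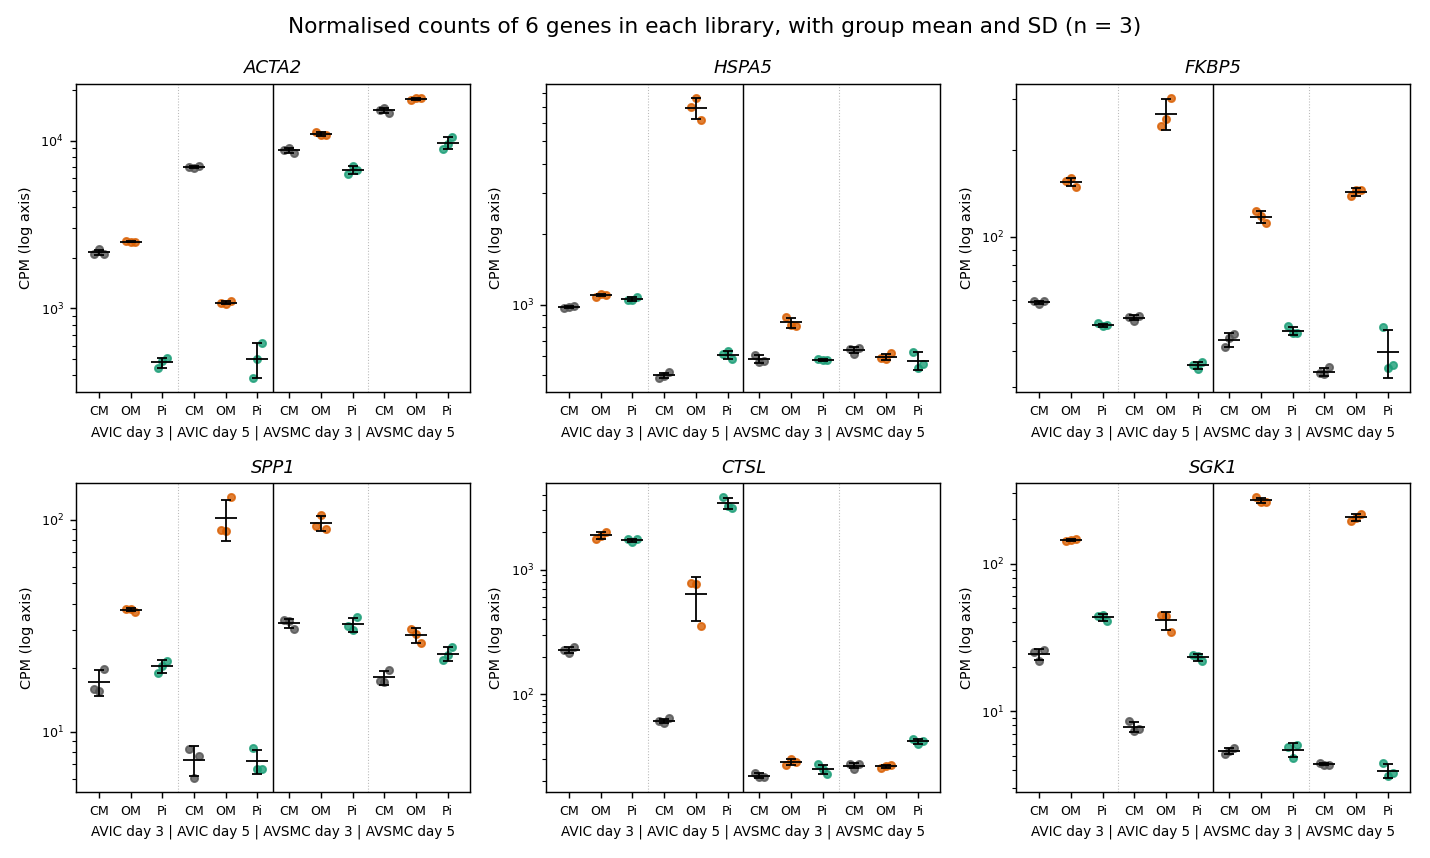
Normalised level in CPM (log axis) of ACTA2, HSPA5, FKBP5, SPP1, CTSL and SGK1 in each library by cell type, medium and day, with points for libraries and bars for the mean and SD (n = 3). HSPA5 reached 6938 ± 734 CPM in AVIC in OM at day 5 against 497 ± 13.4 in CM, and SGK1 206 ± 11.5 CPM in AVSMC in OM at day 5 against 4.37 ± 0.0893 in CM.

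In AVSMC, OM against CM asks how arterial smooth muscle cells responded to osteogenic medium. At day 3 SGK1 (gene ID 100625739, chromosome 1 from 29625786 to 29753619), a kinase gene that glucocorticoids induce, rose 49.8-fold (5.64 ± 0.08, adjusted p = 2.5e-21). ZBTB16 (4.37 ± 0.17, adjusted p = 3.9e-14) and FKBP5 (1.41 ± 0.09, adjusted p = 9.9e-11) rose as well. SPP1 (1.56 ± 0.08, adjusted p = 2.7e-12), MGP (1.24 ± 0.09, adjusted p = 1.1e-09) and MYH11 (0.95 ± 0.05, adjusted p = 3.2e-12) rose, and RUNX2 was not called (0.03 ± 0.10). CYP1A1, a target of the aryl hydrocarbon receptor (-3.83 ± 0.12), PSAT1 (-3.74 ± 0.10) and the Wnt modulator gene SFRP2 (-3.47 ± 0.08) fell. Of 14714 genes, 6093 were called, 3022 higher and 3071 lower, 1115 of them by at least 2-fold. Glucocorticoid-responsive genes rose in 14 and fell in 0 of 19 cases (15 and 0 adjusted over the list alone, adjusted p = 9.09e-09). Among 18 contractile genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 1.84e-05), with MYOCD (2.43 ± 0.13) and DES (1.17 ± 0.11) higher. There were 13 rises and 1 falls among the 20 ERK-responsive genes tested (13 and 1 adjusted over the list alone, adjusted p = 1.92e-06), with DUSP5 (1.68 ± 0.08) and SPRY4 (1.56 ± 0.08) higher. Of 22 cholesterol synthesis genes, 19 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 1.95e-07). Unfolded protein response and ATF4 genes rose in 6 and fell in 18 of 30 cases (7 and 18 adjusted over the list alone, adjusted p = 8.7e-06), with ASNS at -1.97 ± 0.06. Among 15 oxidative stress genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone, adjusted p = 1.95e-05), with FTL at -2.01 ± 0.07. There were 5 rises and 19 falls among the 26 hypoxia and glycolysis genes tested (5 and 19 adjusted over the list alone, adjusted p = 2.49e-05), with ALDOC at -2.46 ± 0.11. These 7 calls held with an estimated correlation. Of 19 bone and mineralisation genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone, adjusted p = 0.037, or adjusted p = 0.126 with an estimated correlation), with BMP4 at 1.31 ± 0.10, and this call also ended without replicate 1 (0.0846) or 3 (0.0522) of every group. Wnt responsive genes rose in 9 and fell in 2 of 17 cases (10 and 2 adjusted over the list alone, adjusted p = 0.00148, or adjusted p = 0.126 with an estimated correlation), with DKK2 at 2.64 ± 0.11. AVSMC OM day 3 replicate 1 differed from its fellows by a chi-square per degree of freedom of 29.31 and 18.96, with 0.856% of its counts from mitochondrial genes against 1.725% and 2.013%. With library totals alone 31.7% of called genes were higher, against 49.6%, and the median of all genes moved by -0.111.

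At day 5 SGK1 in AVSMC stood at 206 ± 11.5 CPM in OM against 4.37 ± 0.0893 in CM (5.57 ± 0.08, adjusted p = 6.9e-21). MGP (gene ID 397206, chromosome 5 from 57665272 to 57669360) rose from 216 ± 7.59 to 771 ± 27.4 CPM (1.84 ± 0.09, adjusted p = 1.3e-12). RUNX2 (0.33 ± 0.09) and SPP1 (0.67 ± 0.09) rose, and NT5E (-1.55 ± 0.09) and SFRP2 (-3.83 ± 0.08) fell. SP7, the osterix transcription factor gene of osteoblasts, averaged 0.704 ± 0.180 CPM in OM against 0.131 ± 0.115 in CM (2.42 ± 0.65, adjusted p = 0.0036). Called genes numbered 5674 of 14714, 3051 higher and 2623 lower, 1103 of them by at least 2-fold. At both days 2087 genes were called higher and 1814 lower in OM. Among 19 glucocorticoid-responsive genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 4.04e-11). There were 19 rises and 0 falls among the 22 cholesterol synthesis genes tested (19 and 0 adjusted over the list alone, adjusted p = 3.79e-10). Of 26 hypoxia and glycolysis genes, 5 rose and 19 fell (5 and 19 adjusted over the list alone, adjusted p = 2e-09), with BNIP3 at -2.38 ± 0.09. Oxidative stress genes rose in 1 and fell in 10 of 15 cases (2 and 11 adjusted over the list alone, adjusted p = 9.59e-07), with NQO1 at -1.80 ± 0.10. Among 30 unfolded protein response and ATF4 genes, 2 rose and 16 fell (2 and 16 adjusted over the list alone, adjusted p = 7.78e-08). These 5 calls held with an estimated correlation, unlike the next 4. There were 22 rises and 0 falls among the 29 interferon-stimulated genes tested (25 and 0 adjusted over the list alone, adjusted p = 1.16e-07, or adjusted p = 0.266 with an estimated correlation), with USP18 at 0.94 ± 0.14. Of 18 contractile genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 3.53e-05, or adjusted p = 0.0719 with an estimated correlation), with DES at 1.96 ± 0.09. Bone and mineralisation genes rose in 10 and fell in 2 of 19 cases (11 and 2 adjusted over the list alone, adjusted p = 0.0197, or adjusted p = 0.11 with an estimated correlation). Among 12 cartilage genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0442, or adjusted p = 0.146 with an estimated correlation). The cartilage call also ended without replicate 3 of every group (0.0955) and with a prior count of 0.5 (0.0555). Library totals alone put 34% of called genes higher, against 53.8%, with a shift of all genes by -0.115.

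The OM response of AVSMC differed between days in 882 genes, 495 more positive and 387 more negative at day 5. ELN (1.24 ± 0.14) was more positive and PTGS2 (-1.67 ± 0.11) more negative. 0 of 37 cell cycle genes were more positive and 16 more negative (0 and 29 adjusted over the list alone, median -0.32, adjusted p = 4.27e-20). Of 26 hypoxia and glycolysis genes, 1 were more positive and 8 more negative (2 and 11 adjusted over the list alone, median -0.24, adjusted p = 3.46e-06). Both calls held with an estimated correlation. The count of genes was 1720 with the compared groups fitted alone, and without the filter on low counts 44.5% of called genes were more positive, against 56.1%. Without AVSMC CM day 3 replicate 1 the majority turned as well, with 256 genes more positive and 405 more negative (38.7% more positive).

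Pi against CM in AVSMC asks how smooth muscle cells responded to phosphate, and at day 3 the changes were few and small. CXCL8 rose from 1.28 ± 0.0888 to 5.53 ± 1.68 CPM (2.07 ± 0.27, adjusted p = 1.2e-04). The metallothionein gene MT-2B (gene ID 396827, chromosome 6 from 18645125 to 18646034) rose from 6.95 ± 0.904 to 19.2 ± 1.23 CPM (1.46 ± 0.12). SLC20A1 (0.29 ± 0.06, adjusted p = 0.005) and NT5E (0.64 ± 0.08, adjusted p = 5.5e-05) rose, while MYH11 (-0.54 ± 0.05, adjusted p = 1.7e-06), ACTA2 (-0.40 ± 0.05, adjusted p = 1.2e-04) and ELN (-0.78 ± 0.10) fell. RUNX2 (0.23 ± 0.09), SPP1 (-0.03 ± 0.08) and MGP (0.11 ± 0.09) were not called. Of 14714 genes, 476 were called, 199 higher and 277 lower, 20 of them by at least 2-fold. Contractile genes rose in 0 and fell in 10 of 18 cases (0 and 15 adjusted over the list alone, adjusted p = 3.13e-20). Among 20 ERK-responsive genes, 9 rose and none fell (15 and 0 adjusted over the list alone, adjusted p = 1.25e-15), with SPRY4 (0.56 ± 0.08) and the cyclin gene CCND1 (0.37 ± 0.04) higher. There were 8 rises and 0 falls among the 19 inflammatory genes tested (11 and 0 adjusted over the list alone, adjusted p = 1.51e-13), with CCL2 (0.83 ± 0.11) and PTGS2 (0.67 ± 0.08) higher. These 3 calls held with an estimated correlation. Of 29 interferon-stimulated genes, 0 rose and 5 fell (0 and 21 adjusted over the list alone, adjusted p = 9.31e-15, or adjusted p = 0.17 with an estimated correlation). Collagen and fibrous matrix genes rose in 2 and fell in 9 of 25 cases (3 and 12 adjusted over the list alone, adjusted p = 5.63e-06, or adjusted p = 0.135 with an estimated correlation). The bone list was not called, as 0 of 19 bone and mineralisation genes rose and 3 fell (0 and 3 adjusted over the list alone, adjusted p = 0.6). The count of called genes was 2330 with the compared groups fitted alone and between 227 and 275 with any 1 of the 6 libraries left out. Library totals alone put 58.7% of called genes higher, against 41.8%.

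By day 5 of Pi in AVSMC, CXCL8 stood at 12.3 ± 2.79 CPM against 1.46 ± 0.460 in CM (3.10 ± 0.23, adjusted p = 2.7e-08). VEGFA (1.12 ± 0.07), SLC20A1 (0.49 ± 0.06, adjusted p = 3.7e-06) and SPP1 (0.37 ± 0.09, adjusted p = 0.0088) rose. ELN (-1.76 ± 0.11, adjusted p = 7.2e-09), the skeletal actin gene ACTA1 (-2.35 ± 0.19) and ACTA2 (-0.64 ± 0.05, adjusted p = 8.0e-08) fell. Called genes numbered 1993 of 14714, 961 higher and 1032 lower, 139 of them by at least 2-fold. At both days 128 genes were called higher and 201 lower in Pi. There were 0 rises and 18 falls among the 18 contractile genes tested (0 and 18 adjusted over the list alone, adjusted p = 1.71e-23), with DES at -1.17 ± 0.10. Of 25 collagen and fibrous matrix genes, 2 rose and 15 fell (3 and 17 adjusted over the list alone, adjusted p = 3.06e-11), with COL1A1 at -0.61 ± 0.06. ERK-responsive genes rose in 12 and fell in 0 of 20 cases (15 and 0 adjusted over the list alone, adjusted p = 6.69e-10), with DUSP4 at 1.23 ± 0.12. Among 19 inflammatory genes, 12 rose and none fell (16 and 0 adjusted over the list alone, adjusted p = 2.86e-14), with IL1A at 1.16 ± 0.11. There were 8 rises and 1 falls among the 20 p53 targets tested (11 and 1 adjusted over the list alone, adjusted p = 0.00111), with SESN2 at 0.70 ± 0.09. These 5 calls held with an estimated correlation, unlike the next 3. Of 30 unfolded protein response and ATF4 genes, 18 rose and 7 fell (18 and 8 adjusted over the list alone, adjusted p = 4.32e-05, or adjusted p = 0.053 with an estimated correlation), with DDIT4 at 1.39 ± 0.13. Oxidative stress genes rose in 7 and fell in 0 of 15 cases (7 and 1 adjusted over the list alone, adjusted p = 0.00626, or adjusted p = 0.0807 with an estimated correlation), with SLC7A11 at 1.11 ± 0.17. Among 22 cholesterol synthesis genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone, adjusted p = 0.00626, or adjusted p = 0.345 with an estimated correlation). The mean of the cholesterol genes was 0.14 while the median and the test pointed down, and the call ended without replicate 1 of every group (0.0682). AVSMC Pi day 5 replicate 1 stood apart, with a chi-square per degree of freedom of 80.44 and 69.24 against its fellows, which differed from each other by 13.73. The main fit shares 1 estimate of spread per gene over all 18 AVSMC libraries. Its calls and p-values for Pi at day 5 may therefore rest on a spread below that of this group. The count of called genes was 1309 without CM day 5 replicate 2, 3087 without Pi day 5 replicate 3 and 419 with the compared groups fitted alone. With library totals alone it was 3177, of which 79.7% were higher, against 48.2%.

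The Pi response of AVSMC differed between days in 179 genes, among them TXNIP (1.62 ± 0.27), DDIT4 (1.24 ± 0.18) and CTGF (-0.88 ± 0.07, adjusted p = 1.8e-06). This count was 781 without Pi day 5 replicate 3, 436 without Pi day 5 replicate 2, 293 without Pi day 5 replicate 1, and between 46 and 115 without any other library. 10 of 30 unfolded protein response and ATF4 genes were more positive and 2 more negative (16 and 5 adjusted over the list alone, median 0.31, adjusted p = 2.07e-05, or adjusted p = 0.0828 with an estimated correlation). No list call held with an estimated correlation here. Library totals alone made 70% of called genes more positive, against 46.4%.

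**Figure D3:**
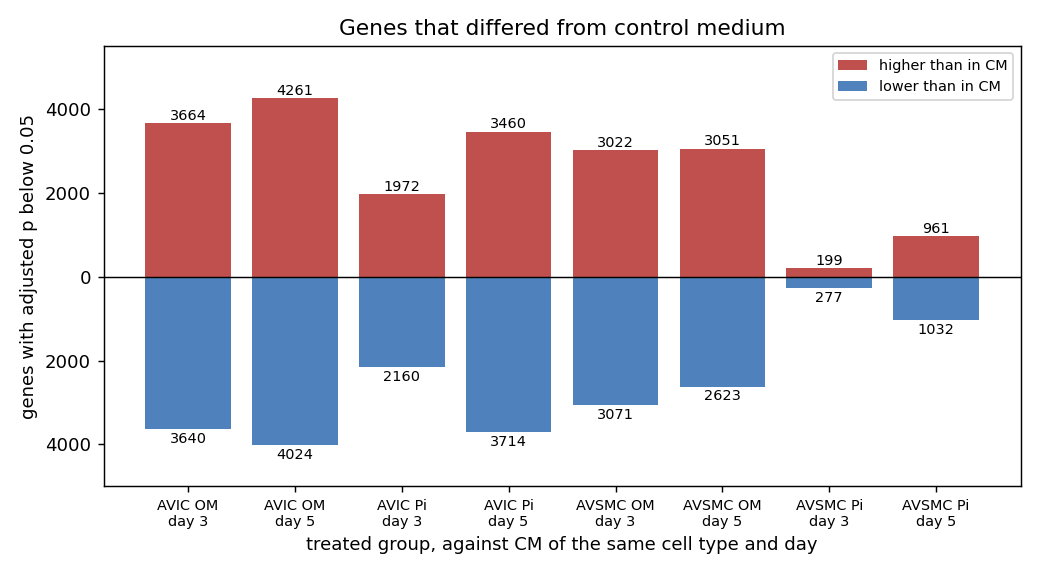
Number of genes called higher (upward bars) and lower (downward bars) than CM at an adjusted p under 0.05, for OM and Pi at days 3 and 5 in AVIC and AVSMC. Counts run from 476 for Pi in AVSMC at day 3 to 8285 for OM in AVIC at day 5.

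Pi against OM asks where the treatments differed from each other. In AVIC at day 3, MYH11 (-5.50 ± 0.18) was lower in Pi, and BMP2 (2.64 ± 0.08), EGLN3 (3.10 ± 0.08) and ASNS (2.30 ± 0.06) were higher. At day 5, HSPA5 (-3.52 ± 0.06), SPP1 (-3.82 ± 0.16) and FKBP5 (-2.92 ± 0.06) were lower in Pi, and PTGS2 (2.91 ± 0.06) was higher. Called genes numbered 7681 at day 3, 3783 higher and 3898 lower in Pi, and 8387 at day 5, 3958 and 4429. Of 18 contractile genes, 1 were higher and 17 lower (1 and 17 adjusted over the list alone, median -1.77, adjusted p = 1.99e-12) at day 3. Unfolded protein response and ATF4 genes numbered 21 higher and 3 lower of 30 tested (21 and 4 adjusted over the list alone, median 0.7, adjusted p = 1.83e-10) at day 3. Among 30 unfolded protein response and ATF4 genes, 5 were higher and 20 lower (5 and 20 adjusted over the list alone, median -0.67, adjusted p = 5.05e-07) at day 5. 2 of 26 collagen and fibrous matrix genes were higher and 22 lower (3 and 22 adjusted over the list alone, median -0.79, adjusted p = 1.09e-09) at day 5, with ELN at -2.90 ± 0.06. Of 13 cardiac and valve positional genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone, median 0.26, adjusted p = 0.0123) at day 5. In AVSMC, SGK1 was lower in Pi at day 3 (-5.62 ± 0.08) and day 5 (-5.70 ± 0.08), as was MGP at day 5 (-1.87 ± 0.09). CXCL8 (5.75 ± 0.34) and NT5E (2.13 ± 0.08) were higher in Pi at day 5. Called genes in AVSMC numbered 6339 at day 3, 3174 higher and 3165 lower in Pi, and 6686 at day 5, 3319 and 3367. Contractile genes numbered 0 higher and 18 lower of 18 tested (0 and 18 adjusted over the list alone, median -0.84, adjusted p = 1.57e-13) at day 5. Among 22 cholesterol synthesis genes, 0 were higher and 21 lower (0 and 21 adjusted over the list alone, median -0.7, adjusted p = 1.01e-10) at day 5. 19 of 26 hypoxia and glycolysis genes were higher and 5 lower (19 and 5 adjusted over the list alone, median 0.86, adjusted p = 3.81e-08) at day 5. These calls, for both cell types, held with an estimated correlation. In AVIC at day 3 the collagen call (7.28e-07) did not (0.128), and the cardiac list was not called (0.245). Library totals alone put 58.5% and 68.1% of called genes higher in AVIC at days 3 and 5, against 49.3% and 47.2%. In AVSMC they put 72.6% and 75.3% higher, against 50.1% and 49.6%, and the largest shift of all genes was 0.205.

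**Figure D4:**
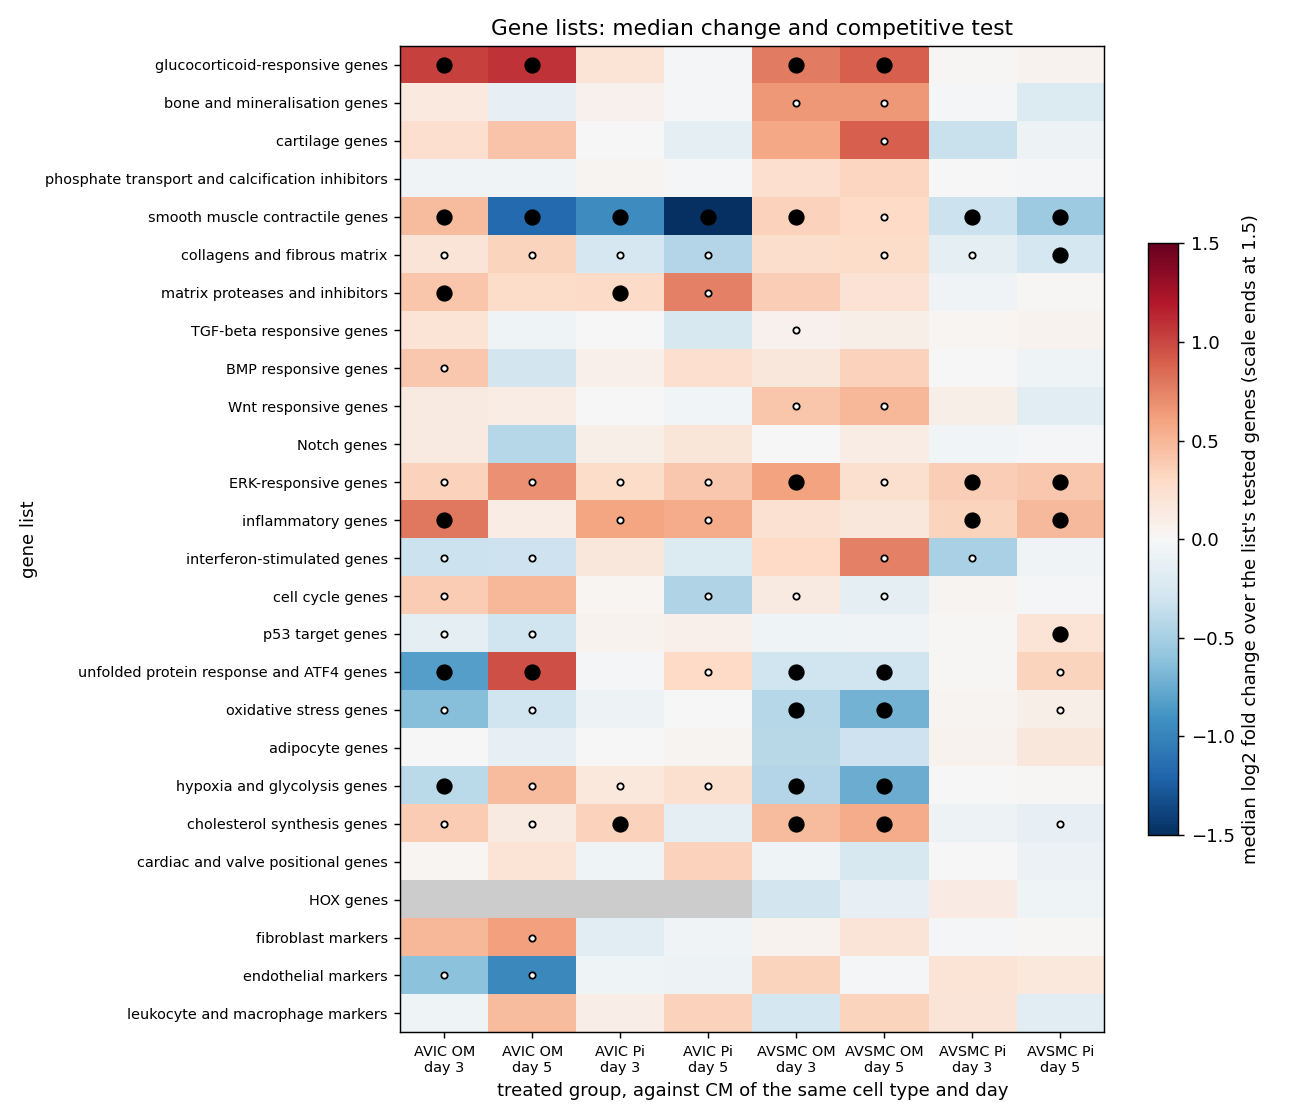
Median log2 fold change of the tested members of each of the 26 gene lists in the 8 comparisons of OM or Pi with CM, with a colour scale ending at -1.5 and 1.5, large black dots for lists called with the preset and the estimated correlation, small white dots for the preset alone and grey for fewer than 5 tested members. Contractile genes in Pi ran from -0.32 in AVSMC at day 3 to -2.09 in AVIC at day 5.

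Control cultures were compared between days to see what changed without either treatment. In AVSMC, the mitotic cyclin gene CCNB1 fell from 128 ± 1.98 to 32.0 ± 2.65 CPM (-2.02 ± 0.07, adjusted p = 4.4e-14), while DES (2.02 ± 0.10), MGP (1.80 ± 0.09) and MYH11 (1.06 ± 0.05) rose. In AVIC, the replication factor gene MCM3 fell (-2.08 ± 0.10), and MYH11 (2.86 ± 0.15) and the cholesterol synthesis gene HMGCS1 (1.20 ± 0.05) rose. Called genes numbered 7456 in AVIC, 3609 higher and 3847 lower at day 5, and 4350 in AVSMC, 2139 and 2211. Among 37 cell cycle genes, 0 rose and 37 fell (0 and 37 adjusted over the list alone, adjusted p = 1.91e-54) in AVSMC. There were 0 rises and 36 falls among the 37 cell cycle genes tested (0 and 36 adjusted over the list alone, adjusted p = 1.51e-20, or adjusted p = 0.343 with an estimated correlation) in AVIC. Of 18 contractile genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 4.08e-09) in AVIC. Contractile genes rose in 17 and fell in 0 of 18 cases (17 and 0 adjusted over the list alone, adjusted p = 7.68e-13) in AVSMC. Among 22 cholesterol synthesis genes, 22 rose and none fell (22 and 0 adjusted over the list alone, adjusted p = 6.84e-21) in AVIC. Apart from the cell cycle call in AVIC, these calls held with an estimated correlation. Library totals alone put 36.6% of called genes higher in AVIC and 32.4% in AVSMC, against 48.4% and 49.2%.

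AVSMC against AVIC in CM gives the baseline from which each cell type responded, with cell type confounded with source and growth medium. At day 3 POSTN, encoding the matrix protein periostin, was lower in AVSMC, at 27.9 ± 1.12 against 4041 ± 32.8 CPM (-7.18 ± 0.09). The cardiac transcription factor gene GATA4 (gene ID 397555, chromosome 14 from 14858470 to 14938156) was lower in AVSMC, by -5.95 ± 0.10. CDH5, encoding the endothelial cadherin, stood at 0.568 ± 0.114 CPM in AVSMC and 47.5 ± 0.482 in AVIC (-6.40 ± 0.14). MYH11 was higher in AVSMC, at 720.5 ± 10.5 against 8.28 ± 0.0567 CPM (6.44 ± 0.11). The positional gene HOXC8 (gene ID 100739594, chromosome 5 from 19222124 to 19225734) had 26.9 ± 2.85 CPM in AVSMC at day 5 and no count in AVIC, at least 1180-fold higher. Called genes numbered 8721 of 15507 at day 3, 4279 higher and 4442 lower in AVSMC, and 8968 at day 5, 4338 and 4630. 23 of 24 HOX genes were higher and 0 lower (23 and 0 adjusted over the list alone, median 7.53, adjusted p = 2.7e-12) at day 3, and the median was 5.13 with the 14 genes at 0 in 1 cell type set to their bound. Of 18 contractile genes, 18 were higher and 0 lower (18 and 0 adjusted over the list alone, median 1.83, adjusted p = 2.49e-16) at day 3. Endothelial markers numbered 0 higher and 12 lower of 14 tested (0 and 13 adjusted over the list alone, median -5.06, adjusted p = 3.69e-09) at day 3, and the median was -4.11 at the bounds. Among 22 cholesterol synthesis genes, 0 were higher and 21 lower (0 and 21 adjusted over the list alone, median -1.13, adjusted p = 2.69e-15) at day 3. 2 of 30 unfolded protein response and ATF4 genes were higher and 26 lower (2 and 26 adjusted over the list alone, median -0.6, adjusted p = 9.85e-09) at day 3. Of 14 cardiac and valve positional genes, 2 were higher and 9 lower (2 and 9 adjusted over the list alone, median -1.42, adjusted p = 0.00532) at day 3. These calls held with an estimated correlation, and the following did not. Interferon-stimulated genes numbered 23 higher and 0 lower of 29 tested (23 and 0 adjusted over the list alone, median 1.61, adjusted p = 6.94e-09, or adjusted p = 0.127 with an estimated correlation) at day 3, and the median was 1.49 at the bounds. Among 37 cell cycle genes, 29 were higher and 0 lower (29 and 0 adjusted over the list alone, median 0.51, adjusted p = 0.000203, or adjusted p = 0.607 with an estimated correlation) at day 5, while at day 3 this list was not called (0.214), except without replicate 3 of every group (0.0162). At day 5 the unfolded protein response call (0.00121) ended with an estimated correlation (0.0896). The cardiac call of day 5 (0.0377) ended with an estimated correlation (0.0748), with a prior count of 0.5 (0.0576) and without replicate 1 of every group (0.0538).

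Whether the treatments acted differently in the cell types was tested as the response in AVSMC minus that in AVIC. For OM at day 5, HSPA5 (-3.89 ± 0.08, adjusted p = 4.7e-29) and SPP1 (-3.12 ± 0.19) responded more positively in AVIC, and ACTA2 (2.90 ± 0.12), MYH11 (3.31 ± 0.13) and MGP (2.82 ± 0.14) in AVSMC. At day 3, SGK1 differed by 3.06 ± 0.12 and RUNX2 by -0.85 ± 0.13. For Pi, ACTA2 differed by 1.78 ± 0.12 at day 3 and 3.13 ± 0.12 at day 5, and the cathepsin gene CTSL by -5.14 ± 0.27 at day 5. The OM response differed in 3480 genes at day 3, 1896 more positive in AVSMC and 1584 more negative, and in 6249 at day 5, 3151 and 3098. The Pi response differed in 2269 genes at day 3, 1241 more positive in AVSMC and 1028 more negative, and in 3691 at day 5, 2104 and 1587. 2 of 30 unfolded protein response and ATF4 genes were more positive and 27 more negative (2 and 27 adjusted over the list alone, median -1.92, adjusted p = 2.97e-27) for OM at day 5. Of 18 contractile genes, 16 were more positive and 1 more negative (16 and 1 adjusted over the list alone, median 1.16, adjusted p = 3.12e-12) for OM at day 5. Hypoxia and glycolysis genes numbered 3 more positive and 20 more negative of 26 tested (3 and 20 adjusted over the list alone, median -1.24, adjusted p = 1.37e-14) for OM at day 5. Among 18 contractile genes, 10 were more positive and 0 more negative (11 and 0 adjusted over the list alone, median 0.73, adjusted p = 4.78e-10) for Pi at day 3. 15 of 18 contractile genes were more positive and 0 more negative (16 and 0 adjusted over the list alone, median 1.73, adjusted p = 3.72e-19) for Pi at day 5. Of 22 cholesterol synthesis genes, 0 were more positive and 15 more negative (0 and 18 adjusted over the list alone, median -0.42, adjusted p = 5.79e-14) for Pi at day 3. All of these held with an estimated correlation, and no list call did for OM at day 3. For Pi at day 5 the cholesterol list was not called (0.695). The count for Pi at day 3 was 4154 with the compared groups fitted alone, and for OM at day 3 library totals alone made 36.6% more positive, against 54.5%. Across the 14038 genes tested in both cell types, OM at day 3 called 1733 genes higher in both, against 735.8 if the calls were independent, and 1711 lower in both, against 757. At day 5 these numbers were 1210 against 858.9 and 1073 against 716.1, with 624 genes higher in AVIC and lower in AVSMC and 780 the other way round. For the opposite calls no number expected if independent was computed, so their counts alone do not show opposed responses. For Pi at day 5, 571 genes were called higher in both, against 227.7, and 673 lower in both, against 259.7.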

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

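The tests of the stress gene, endothelial and phosphate patterns were chosen only after their results had been seen, while the gene lists, the tests of the differences and the counts over other splits were set before. Apart from the endothelial markers, every pattern here came up because a response differed between days or between cell types by a test of the difference itself.

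The clearest such difference was in the unfolded protein response and ATF4 genes of AVIC in OM, which were lower than in CM at day 3 and higher at day 5, with a median difference between days of 2.32. If the libraries described as day 5 were day 3 cultures, as their titles say, cell cycle genes would differ little between them and the day 3 libraries, yet their median change was -1.8, against -2.0 in CM and -2.36 in Pi. This cell cycle median includes AVIC OM day 5 replicate 3, which stood apart, and was not recomputed without it. Without replicate 3 of every group, the cell cycle list was called higher in OM than in CM at day 5 (adjusted p = 8.3e-09, against 0.118). The rise of the stress genes was not carried by 1 library, since their median at day 5 was 0.94 or more whichever AVIC OM day 5 library was left out. With library totals alone that median was 0.92, against -0.86 at day 3. In CM the test of the unfolded protein response and ATF4 list pointed down from day 3 to day 5. It was not called in the main setting (adjusted p = 0.0542) but was without the filter (0.0344). Part of the difference between days may therefore come from CM. A change of the cells' stress state with time in OM may underlie the pattern, as a hypothesis found and tested on the same data. The response also differed between the cell types, with a median of -1.92 for OM at day 5 in AVSMC minus AVIC. That difference uses the same AVIC libraries of day 5, so it is not a separate observation. The lack of stated replicate origins leaves a shared handling of those cultures untested.

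Endothelial markers in AVIC, CDH5 among them at 47.5 ± 0.482 CPM in CM at day 3, were mostly lower in OM, which could reflect a smaller share of endothelial cells in those cultures. Such a share would move all markers alike, but at day 3, 4 of 11 markers with under 1 CPM in AVSMC lay more than 2 standard errors from their weighted mean of -0.74. These were CDH5 (-0.62 ± 0.06), EMCN (-1.76 ± 0.20), NOS3 (-2.16 ± 0.17) and PLVAP (5.34 ± 0.46). CDH5 nevertheless lay close to that mean, and PLVAP started from 10 counts over the CM libraries of day 3. EMCN and NOS3 fell further than the mean, which a share that moved all markers alike would not give. The test assumes such equal movement, so it does not exclude a smaller share. Regulation within the cells stays open as an untested hypothesis.

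Fewer genes were called for Pi at day 3 in AVSMC (476) than in AVIC (4132), and the responses differed in 2269 genes by the test of the difference. With the compared groups fitted alone the counts were 2330 and 5310, and AVIC had 2.28 times as many genes in place of 8.68. The spread of the AVSMC libraries outside the comparison may account for this part of the gap. That fit also changed the filter, the TMM factors and the residual degrees of freedom, and these were not tested apart. Spread as the whole account was argued against by the SD of the log2 changes beyond their standard errors, which in AVSMC was 0.456 of that in AVIC over 10215 genes, and by their SD without that allowance, 0.164 against 0.3. A lower depth of the AVSMC libraries was argued against as well, since their mean total was 1.11 times that of AVIC. A weaker response of AVSMC to phosphate may explain the rest, but cell type is confounded with source and medium, and the labels do not give the phosphate content of either medium.

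The difference between days was called in 6249 genes for OM in AVIC, 2834 for Pi in AVIC, 882 for OM in AVSMC and 179 for Pi in AVSMC. In AVIC in OM the medians of contractile and hypoxia and glycolysis genes differed between days by -1.80 and 0.86. For Pi in AVIC the medians were -0.92 for contractile, 0.34 for ERK-responsive, 0.36 for unfolded protein response and ATF4 and -0.47 for cholesterol synthesis genes. The contractile median of AVIC in CM itself rose by 0.99 between days, and cholesterol synthesis genes rose in CM as well. The ERK-responsive list was called lower at day 5 in CM (adjusted p = 0.00289, or adjusted p = 0.208 with an estimated correlation). The unfolded protein response and ATF4 list pointed down in CM without being called (adjusted p = 0.0542). These changes in CM enter the differences between days. For OM in AVSMC they were -0.32 for cell cycle and -0.24 for hypoxia and glycolysis genes. Between cell types, the OM response differed in 3480 genes at day 3 and 6249 at day 5, and the Pi response in 2269 at day 3 and 3691 at day 5. For OM at day 5 the medians were 1.16 for contractile, 0.43 for p53 target and -1.24 for hypoxia and glycolysis genes. For Pi at day 3 they were 0.73 for contractile genes, -0.34 for matrix proteases and inhibitors and -0.42 for cholesterol synthesis genes. For Pi at day 5 they were 1.73 for contractile genes and -0.38 for matrix proteases and inhibitors.

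The libraries of each interaction were also split in other ways, 100 times each with the real split counted. At least as many genes as in the real split came from 2 splits for OM between days in AVIC (6249 genes, 8697 in the highest other split). The same number of splits did so for OM at day 5 between cell types (6249 and 7476) and for Pi at day 3 between cell types (2269 and 2403). The splits numbered 8 for Pi between days in AVIC (2834 genes and 7379 in the highest other) and 10 for OM between days in AVSMC (882 and 7680). They numbered 11 for Pi between days in AVSMC (179 and 1824), 10 for OM at day 3 between cell types (3480 and 7840) and 7 for Pi at day 5 between cell types (3691 and 6127). Every split that gave more genes than the real one kept or swapped the treatment labels of 1 day or 1 cell type whole, which points to a structure of the samples, namely the treatment effect itself. Splits that mixed the labels in both gave at most 24 genes, but such mixing also removes the treatment effect. The splits of the interactions therefore cannot tell whether a difference between days or cell types arose by chance. No conclusion on chance is drawn from them. For comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05, and in each only 1 split, the real one, gave as many genes. Every other split mixed libraries of the compared groups, which moves any real difference into the spread. Low counts in those splits therefore say nothing on chance. The highest other split gave 84 genes for Pi in AVSMC at day 5 (real 1993), 4 for Pi against OM in AVIC at day 5 (8387), 1 for OM in AVSMC at day 3 (6093), 1 for Pi against OM in AVSMC at day 5 (6686) and 0 in the other 12 comparisons. The real counts in those 12 ran from 476 for Pi in AVSMC at day 3 to 8968 for AVSMC against AVIC at day 5.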

How the results depend on the processing

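Library totals in place of TMM factors were tried only after the results had been seen, and every other test here had been planned. Counts of called genes stayed within 1.5 times the main count except as follows, and the cause was not tested unless stated. With the compared groups fitted alone, and so with fewer libraries behind each estimate of spread and none from the other groups, the count was 2330 for Pi in AVSMC at day 3 (main 476), 419 at day 5 (1993), 51 for its change between days (179), 1720 for the change of OM in AVSMC between days (882) and 4154 for Pi at day 3 between cell types (2269). In 1 fit of 36 libraries it was 771 for Pi in AVSMC at day 3 and 578 for its change between days, and with the DESeq2 Wald test 796 and 429. With library totals alone it was 3177 for Pi in AVSMC at day 5. Leaving out 1 library gave 227 to 275 genes for Pi in AVSMC at day 3, 1309 to 3087 at day 5 (the lowest without CM day 5 replicate 2, the highest without Pi day 5 replicate 3) and 46 to 781 for its change between days (the highest without Pi day 5 replicate 3). A block for replicate number moved no count by over 1.5 times and gave 436 genes for Pi in AVSMC at day 3 and 1791 at day 5. The deviations of libraries from their group means in log2 CPM were compared between libraries of the same number in 2 groups. They correlated by at most 0.0608 in 42 pairs, all under the limit of 0.1 set for pairing. List calls in the comparisons of OM or Pi with CM numbered 79 of 204, and 33 with an estimated correlation, all among the 79. They numbered 81 with the block, 79 with DESeq2 size factors, 78 with a prior count of 0.5, 81 of 208 without the filter, 87 with library totals alone and 78 to 84 without 1 replicate number. Of the named genes' results, 2329 kept their direction and side of the threshold and 3 fell short of it with DESeq2 size factors, 2324 and 7 with the Wald test, 2320 and 12 without the filter, 2322 and 10 with the block, 2252 and 61 with the compared groups fitted alone, 1714 and 23 in 1 fit of 36 libraries, and 2299 and 26 with library totals alone. With 1 library left out 17433 kept both and 470 fell short, and under each of these settings at most 7 newly passed it. No named gene reversed under any of these. With limma on FPKM 2269 results kept both and 55 fell short with a pseudocount of 0.1, and 2255 and 62 with 1. With a pseudocount of 1 the log2 change reversed for BMPR1B for OM in AVIC at day 3 (-0.083). For OM at day 3 between cell types it reversed for DES (0.16), CLIC6 (0.805), COL11A1 (-0.461) and COMP (0.023), and for Pi between cell types for genes that include CASQ2 at day 3 (-0.217) and LDB3 (-0.154) and DLX3 (0.205) at day 5. With a pseudocount of 0.1 it reversed for BMPR1B (-0.164) and CLIC6 (0.55). In simulated data, where only well counted genes were changed, a log2 change of 0.5 was recovered in 13.4% of changed genes for the change of Pi in AVSMC between days and in 20.9% for Pi at day 3 between cell types.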

Other observations

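The test of the glucocorticoid hypothesis was written before its result was seen, and no test in this part was chosen afterwards. Some genes outside the main account changed strongly, and the responses of CTSL, MMP1 and ANKRD1 differed between the cell types. The cathepsin gene CTSL, a lysosomal protease, stood in AVIC at 226 ± 13.4 CPM in CM, 1881 ± 126 in OM and 1722 ± 53.1 in Pi at day 3, and at 61.2 ± 2.69, 633 ± 243 and 3391 ± 356 CPM at day 5. In AVSMC it stood at 26.7 ± 1.26, 26.4 ± 0.716 and 41.9 ± 2.08 CPM at day 5, and the Pi response differed between cell types by -5.14 ± 0.27. MMP1, an interstitial collagenase gene, rose in OM in AVIC from 112 ± 12.3 to 399 ± 18.5 CPM at day 3 and fell in AVSMC from 219.9 ± 6.44 to 26.9 ± 1.31 CPM, a difference of -4.87 ± 0.18. ANKRD1, a stretch-responsive muscle gene, fell in AVIC from 49.8 ± 1.71 to 4.71 ± 0.878 CPM in OM at day 5 and stood in AVSMC at 271 ± 6.41 CPM in OM against 20.8 ± 2.88 in CM, a difference of 7.10 ± 0.16. ELN, encoding elastin, was higher in OM in AVIC at day 5, at 79.8 ± 2.38 against 30.1 ± 1.52 CPM, and lower in Pi in AVSMC, at 43.5 ± 7.31 against 147 ± 20.7 CPM. The tissue inhibitor gene TIMP1 rose in OM in AVSMC from 286 ± 10.5 to 1995 ± 64.1 CPM at day 3, a log2 change of 2.80 ± 0.07. The 10 genes with the highest counts took 7.48% of counts in AVIC in Pi at day 5 and 17.07% in AVSMC in OM at day 5, the lowest and highest of the group means.

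Osteogenic media often contain dexamethasone, a synthetic glucocorticoid, but the labels do not give the composition of the OM used here. The hypothesis that this OM held a glucocorticoid predicted that the share of glucocorticoid-responsive genes higher in OM in all 4 comparisons with CM would be at least 3 times that among all genes tested in both cell types. The share was 63.2% (12 of 19 genes) against 5.08% (713 of 14038), 12.4 times as high, with a one-sided hypergeometric p of 9.77e-12, which treats genes as independent. FKBP5, TSC22D3, PER1, ZBTB16, KLF15, DUSP1, MAOA, SGK1, ANGPTL4, CRISPLD2, NFKBIA and SAMHD1 were the 12 genes. The next highest share was 45.5% (10 of 22) for cholesterol synthesis genes. These values are consistent with a glucocorticoid in OM, which the data cannot show directly, and some of the 12 genes also respond to other stimuli. Of the genes named in this part, ANKRD1, TIMP1, CRISPLD2, NFKBIA, FKBP5 and ZBTB16 overlap another annotated gene.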
